A study of Mus musculus with 23 samples.

How the data were processed

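The samples were NKp46+ cells sorted from collagenase-digested skin, skin lesions and draining lymph nodes of FVB/N mice, with 1 array each. Per the labels' protocols, 0.05 µg of RNA was amplified and labelled with the single dye Cy3. The 23 arrays lay on 5 slides. Group and replicate number were taken from the sample titles. For skin of tumor mice replicate 3 the description names a different group, and its title was used. The labels do not say that replicates are separate animals, so the p-values measure the spread between samples, pooled over all groups, which may be technical.

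Per the file headers, the images were read with Agilent Feature Extraction 10.7.3.1, which wrote for each spot a processed intensity after spatial detrending and background adjustment, with a surrogate value for spots at background, and no scaling between arrays. The authors also deposited a table of log2 values of the same arrays. Its columns had medians of 6.63 to 6.83. They correlated at r of 0.962 to 0.985 with log2 scanner values of their own array, which 11 of 23 matched best. The submitters' notes name limma with no version or step, so that table's method, scale and centring stay unknown. Slides explained 52.1% of the variance within groups in the scanner values used here and 1.92% in that table. Slide may have been removed there, so p-values from it may be too small. RNA integrity numbers were identical within every group and so could not be told apart from it.

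The main values were log2 of the processed intensity minus the array's 75th percentile of it over non-control spots. Of 62976 spots, 59305 were not controls, and spots marked as outliers by the scanner software were set to missing. The 55681 probes were named by accession for 27325, by symbol for 3523 and by synonym for 551, through a table of mouse genes of assembly GRCm38.p6, and 24282 kept the name in the files. The brightest probe over all arrays stood for each of 34740 names, and spots of a probe were averaged. Members of gene families with near-identical sequences, such as the granzymes D to G, the Klra receptors and immunoglobulin segments, can share signal and are uncertain as single genes.

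Values at background on some arrays of a group entered as measured, which leaves such differences uncertain in size. All arrays entered a single limma 3.58.1 fit of group means (R 4.3.3), with contrasts for each comparison, a variance trend and Benjamini-Hochberg adjustment within a comparison over genes well above background on every array of at least 1 of its groups. A gene was called at an adjusted p under 0.05. Where a gene was well above background on no array of a group, the difference is also given as "at least N-fold" where this bound is above 1, from the mean of the brighter group over that of the dimmer group, in which each array's signal was raised to its lowest signal among spots well above background where it lay under it. Skin against lymph node compared the means of the tumor, papilloma and PMA-only states. The difference of lesion effects compared tumor lesions minus skin of tumor mice with papilloma lesions minus skin of papilloma mice. Naive skin had 1 array and no test.

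Lists of genes for lineages, receptors, effector functions, proliferation, stress and metabolism, and lists of markers for other cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were tested (not so for gamma-delta T cells), with adjustment over lists within a comparison. Adjusted p-values with an estimated correlation stand beside them, and 3 of 126 called list shifts kept the call with it. For each list the counts of called members are given over all genes tested and adjusted over the list alone.

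The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between groups, with ordinary symbols (the largest changes among called genes for skin against lymph node and for the difference of lesion effects), up to 4 called members per list with the largest changes, and a set of key NK cell and ILC genes, called or not, where their list is discussed. Where fewer than 5 genes were called, all called genes and the 5 with the smallest p could be named. The text names fewer than the rule allows, largest first except for a few genes left out on request.

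The alternatives tried were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, the mean of all probes of a gene (probe means), slide as a block, replicate number as a block, the authors' table and leaving out each replicate in turn. Same-numbered samples deviated together in 5 comparisons of 3 pairs, with correlations of 0.137 to 0.709. Numbers follow the slides in part.

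The fit was tried on simulated data of 7 comparisons, with 50 genes changed per fold size. At log2 changes of 1, 2, 3 and 4 it recovered 34%, 80%, 90% and 98% for tumor lesions against skin of tumor mice. For papilloma lesions against skin of papilloma mice it was 26%, 72%, 74% and 96%. Real shares may be lower, given the slide effects.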

Results

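Gene expression was measured in innate lymphoid cells that carry NKp46, the product of Ncr1, sorted from the skin, skin lesions and draining lymph nodes of FVB/N mice. The mice were painted with DMBA, a carcinogen that starts skin tumors, and then repeatedly with PMA, a phorbol ester that promotes them. The groups were tumor lesions (n = 3), papilloma lesions (n = 2), skin of mice with tumors (tumor mice, n = 3) and with papillomas (papilloma mice, n = 3), skin of mice given PMA only (n = 2) and naive skin (n = 1). To these came draining lymph nodes of tumor mice, papilloma mice and PMA-only mice (n = 3 each). For naive skin the tissue label reads untreated and the design text describes solvent and PMA. Differences below are on the log2 scale with their standard error, and p-values are those of limma.

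The share of spots well above background lay between 40.3% and 67% on 22 arrays and was 88.7% on papilloma replicate 2, which also had 485 non-uniform spots against at most 54 elsewhere. The arrays of slide 2 (tumor replicate 3 and the third skin sample of tumor and of papilloma mice) were the dimmest, with shares of 40.3% to 45.1%. Over 10579 genes, replicates correlated at r between 0.904 and 0.992 across genes, which are not independent replicates.

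**Figure D1:**
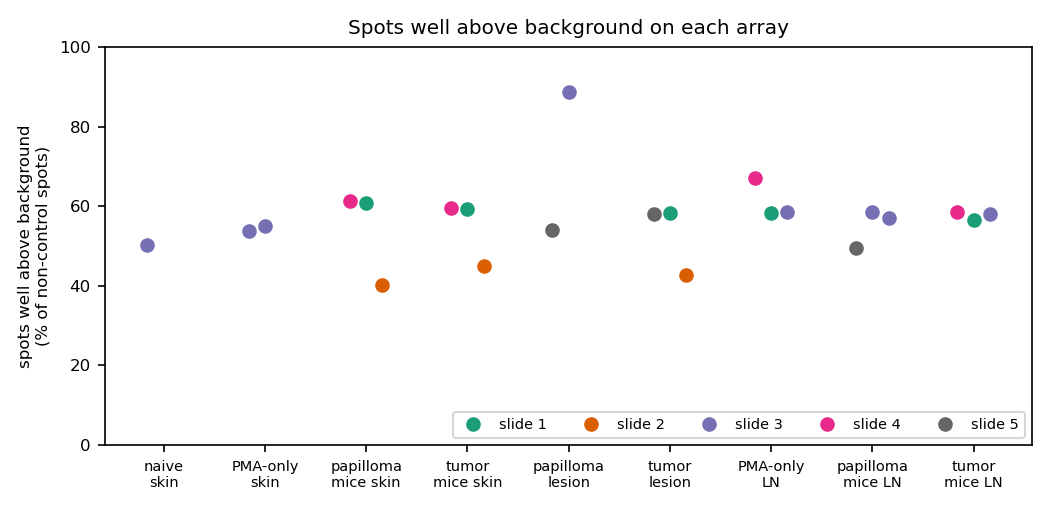
Percent of spots well above background on each of the 23 arrays, coloured by slide. Papilloma replicate 2 stands at 88.7%, all other arrays between 40.3% and 67%.

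Skin and lymph node cells were compared to show how NKp46+ cells of the skin of tumor, papilloma and PMA-only mice (8 arrays) differ from those of the draining nodes (9 arrays). Of 22217 genes tested, 3943 were higher and 4086 lower in skin. Integrins and receptors that hold lymphocytes in tissue rose. Itgae, an integrin that binds epithelial E-cadherin, rose by 4.62 ± 0.576 (adjusted p = 8.12e-06) and Itga1, a collagen receptor, by 3.58 ± 0.272 (adjusted p = 3.42e-08). So did the skin-homing chemokine receptor Ccr8 by 4.07 ± 0.367 (adjusted p = 2.25e-07) and Cd69, which opposes exit from tissue, by 2.62 ± 0.242 (adjusted p = 2.82e-07). Of 17 ILC1 and residency genes 11 rose and 2 fell, and 12 and 2 adjusted over the list alone. Their median was 1.58 (adjusted p = 4.88e-06, or 0.137 with an estimated correlation). The egress receptor S1pr1 fell by 2.78 ± 0.414 (adjusted p = 5.03e-05) and its relative S1pr5 by 1.54 ± 0.129 (adjusted p = 1.02e-07). The chemokine receptor Cxcr4 rose by 2.59 ± 0.265 (adjusted p = 9.46e-07). Homing and egress receptors counted 2 higher and 8 lower of 16, and 3 and 8 adjusted over the list alone, and their shift was not called. Their median was −0.51 (adjusted p = 0.0996, but under 0.05 with normexp, without the filter, with slide as a block and without slide 2). Il7r, the interleukin 7 receptor, fell by 2.21 ± 0.332 (adjusted p = 5.6e-05) and Kit, the stem cell factor receptor, by 2.38 ± 0.182 (adjusted p = 3.49e-08). The lineage genes Ncr1 (−0.03, adjusted p = 0.88), Eomes (−0.14, adjusted p = 0.573) and Tbx21 (0.36, adjusted p = 0.135) were not called (Ncr1 was under quantile normalization and, like Eomes, in the authors' table), and 16 conventional NK cell genes (4 higher, 5 lower) showed no called shift. Their median was −0.187 (adjusted p = 0.31, and 0.0289 with normexp).

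Effector and inhibitory genes were higher in skin. Areg, a growth factor of tissue repair, rose by 6.32 ± 0.376 (adjusted p = 1.54e-09), at least 17.9-fold. Chemokines rose with it: Ccl4, which attracts T cells and monocytes, by 3.04 ± 0.175 (adjusted p = 1.24e-09) and Ccl1, a ligand of Ccr8, by 3.86 ± 0.491 (adjusted p = 1.03e-05). Of 18 cytokine and chemokine genes 11 rose and 1 fell, also adjusted over the list alone. Their median was 0.884 (adjusted p = 0.000182, or 0.204 with an estimated correlation). The inhibitory receptors Pdcd1 (PD-1) and Ctla4 rose by 3.56 ± 0.512 (adjusted p = 3.61e-05) and 3.49 ± 0.419 (adjusted p = 5.48e-06). Of 16 inhibitory receptors 10 rose and 2 fell, also adjusted over the list alone. Their median was 0.745 (adjusted p = 0.00954, or adjusted p = 0.141 with an estimated correlation, and adjusted p = 0.2 with normexp background correction). Among the granule proteases Gzmc rose by 4.04 ± 0.317 (adjusted p = 4.72e-08), Gzmb rose by 1.12 ± 0.164 (adjusted p = 4.13e-05) and Gzmm fell by 1.95 ± 0.175 (adjusted p = 2.11e-07). Of 13 cytotoxic effectors 8 rose and 1 fell, also adjusted over the list alone. Their median was 0.511 (adjusted p = 0.00861, or 0.31 with an estimated correlation). This call was lost under quantile normalization (adjusted p = 0.0785), normexp (adjusted p = 0.194) and in the authors' table (adjusted p = 0.0731). Of 30 cell cycle genes 21 rose, also adjusted over the list alone, such as Ube2c by 1.99 ± 0.203 and Ccnb1 by 1.93 ± 0.202. Their median was 1.13 (adjusted p = 7.67e-11, or 0.227 with an estimated correlation). Interferon-stimulated genes went the other way, 14 of 29 lower, and 14 lower and 1 higher adjusted over the list alone, with the antiviral genes Ifit3 down by 2.08 ± 0.482 and Ifih1 down by 2.00 ± 0.331. Their median was −0.683 (adjusted p = 0.000565, or 0.489 with an estimated correlation).

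Genes that respond within an hour to stimulation or heat also stood higher in skin. Of 23 immediate-early and heat shock genes 18 rose, and 19 adjusted over the list alone, Nr4a3 by 4.88 ± 0.335 and Atf3, a stress-response transcription factor, by 4.58 ± 0.437. Their median was 1.79 (adjusted p = 6.07e-13, or 0.0698 with an estimated correlation). Of 15 NF-kB targets 9 rose and 2 fell, and 10 and 3 adjusted over the list alone, with Tnfaip3 up by 2.89 ± 0.281 and Cd83 by 2.86 ± 0.362. Their median was 1.18 (adjusted p = 0.000565, or adjusted p = 0.371 with an estimated correlation, and adjusted p = 0.0638 with normexp). Markers of other skin cells rose beside all of these groups. All 11 fibroblast markers rose, also adjusted over the list alone, with the matrix genes Dcn, Sparc and Col3a1 up by 7.84 ± 0.587, 6.47 ± 0.631 and 6.19 ± 0.499 (Col3a1 at least 55.1-fold). Their median was 4.17 (adjusted p = 7.11e-11, or 0.137 with an estimated correlation). Of 13 keratinocyte markers 8 rose, also adjusted over the list alone, Krt15 by 5.90 ± 0.951 (at least 18.5-fold) and Krt17 by 5.76 ± 0.898. Their median was 2.17 (adjusted p = 0.000315, or 0.352 with an estimated correlation). The hair keratins Krt35 and Krt71 rose by 8.20 ± 1.8 (Krt35, at least 62.2-fold) and 7.16 ± 1.64. All 6 mast cell and basophil markers rose, also adjusted over the list alone (median 2.96, adjusted p = 0.00137, or adjusted p = 0.137 with an estimated correlation), and 4 of 12 dendritic and Langerhans cell markers, also adjusted over the list alone (median 0.78, adjusted p = 0.0307, or adjusted p = 0.487 with an estimated correlation), a call lost with normexp, with slide as a block, in the authors' table, without the filter on dim probes, with probe means and without 4 of the 17 replicates in turn. The mast cell proteases Cpa3 and Mcpt4 rose by 3.23 ± 0.924 and 3.23 ± 0.972. Of 5 erythroid genes 4 rose, and 5 adjusted over the list alone (median 2.37, adjusted p = 0.000287, or adjusted p = 0.227 with an estimated correlation), with the globin Hbb-b2 up by 2.58 ± 0.297. Retnla, a product of alternatively activated macrophages, rose by 7.25 ± 1.02. Among the largest falls were Syt10 (−5.22 ± 0.921), Cpne4 (−4.46 ± 0.374), the follicle-homing receptor Cxcr5 (−3.95 ± 0.489), the neutrophil gene S100a9 (−3.71 ± 1.17), the receptor Gpr15 (−3.66 ± 0.276) and the Notch regulator Dtx1 (−3.65 ± 0.261).

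**Figure D2:**
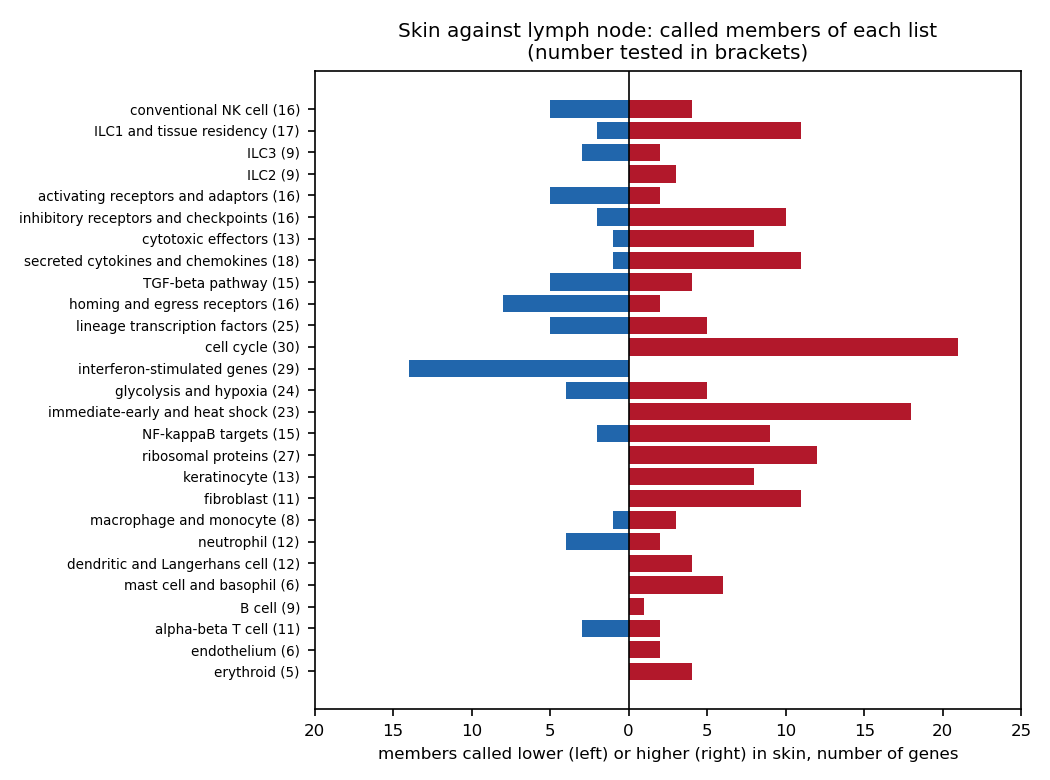
Called members of each gene list in skin against lymph node, higher to the right and lower to the left, with the number tested in brackets. All 11 fibroblast markers and 18 of 23 immediate-early and heat shock genes were higher in skin, 14 of 29 interferon-stimulated genes lower.

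Within the slides that held both tissues, 3614 of the 3943 higher genes and 4059 of the 4086 lower genes kept their direction on slide 1, 3909 and 4084 on slide 3, and 3930 and 4059 on slide 4. Normexp moved the median of all genes by 0.181 and called 12316 genes, 63.8% of them higher against 49.1% here. Of the 42 called genes named, 40 kept the call with slide as a block and without PMA-only skin replicate 2 (Cpa3 and Mcpt4 lost it each time), and 41 kept it without PMA-only skin replicate 1 (S100a9 lost it).

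Tumor lesions were compared with the skin of tumor mice (n = 3 each) to show what changes in NKp46+ cells inside a tumor. Of 17873 genes tested, 39 were higher and 86 lower in the lesions. The largest rises were those of 4 granzymes, serine proteases of cytotoxic granules, whose probes lie near each other on chromosome 14 of mm9. Gzmd rose by 6.37 ± 1.05 (adjusted p = 0.00754), from −4.64 (SD 1.27) to 1.73 (SD 2.17) relative to the array's 75th percentile. Rises of the same order were those of Gzmg by 6.31 ± 0.81 (adjusted p = 0.00253), Gzme by 6.01 ± 0.801 (adjusted p = 0.00292) and Gzmf by 5.74 ± 0.951 (adjusted p = 0.00812). Their probes can share signal. Of 3 skin arrays Gzmd and Gzmg were well above background on 1 and Gzmf on 2, so the sizes and their order are uncertain. Of the other cytotoxic genes Gzma (−0.42, adjusted p = 0.873, called in the authors' table), Gzmb (0.11, adjusted p = 0.988) and Prf1, which codes for perforin (0.19, adjusted p = 0.979), were not called. The 16 cytotoxic effectors counted the 4 rises and no fall, and 4 rises and 1 fall adjusted over the list alone. Their median was 0.114 (adjusted p = 0.000653, or 0.198 with an estimated correlation). Kit rose by 1.95 ± 0.303 (adjusted p = 0.00596), Nt5e, the CD73 enzyme that makes adenosine, by 1.497 ± 0.278 (adjusted p = 0.0152), and Pmepa1, a gene induced by TGF-beta, by 2.42 ± 0.425 (adjusted p = 0.011). Krt6b, a keratin of activated epidermis, rose by 4.72 ± 0.527 (adjusted p = 0.000636) and the macrophage marker Cd68 by 1.85 ± 0.389 (adjusted p = 0.0309). The enzymes Ugt1a10 (2.89 ± 0.598) and Dao (2.85 ± 0.526) and the interferon-stimulated Oasl2 (2.66 ± 0.538) completed the largest rises.

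**Figure D3:**
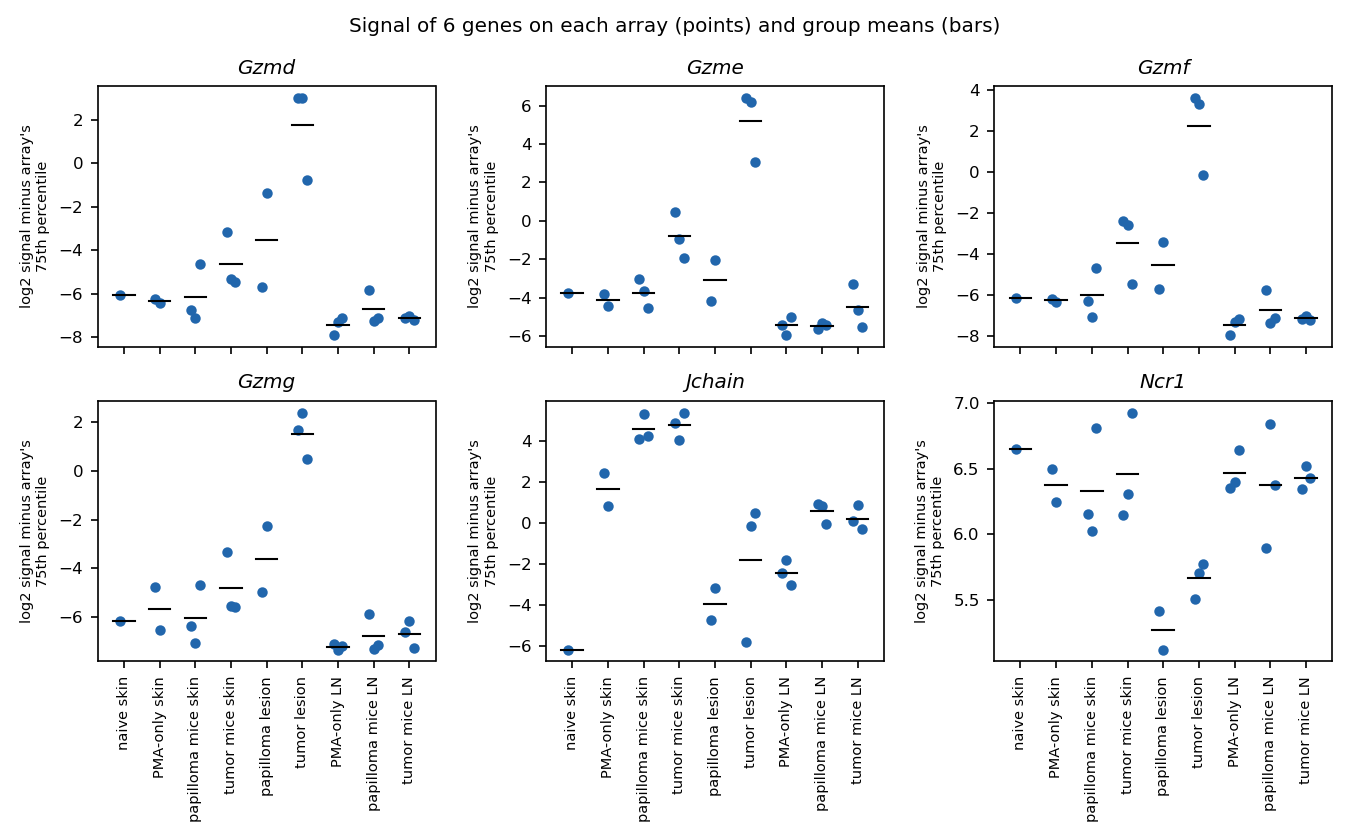
Log2 signal relative to the array's 75th percentile of Gzmd, Gzme, Gzmf, Gzmg, Jchain and Ncr1 on each array, with bars at the group means. The mean of Gzmd is 1.73 in tumor lesions and −4.64 in the skin of tumor mice.

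The largest fall was that of Jchain, which joins secreted IgM and IgA in plasma cells, by 6.59 ± 1.05 (adjusted p = 0.00711), from 4.76 (SD 0.671) to −1.83 (SD 3.48). Immunoglobulin transcripts, a class chosen after the values were seen, fell beside it: 24 of 60 tested were lower and 0 higher (median −3.68, with normexp −1.84 and in the authors' table −2.39). The median of 8 B cell markers was −1.75 (adjusted p = 0.000384, or adjusted p = 0.116 with an estimated correlation), with no called member and 1 lower adjusted over the list alone. Cxcl13, which attracts B cells, was at least 2.84-fold lower (−3.59 ± 0.755, adjusted p = 0.0309). Of 16 cytokine and chemokine genes 2 fell, with 2 lower and 1 higher adjusted over the list alone, and their shift was not called (median 0.273, adjusted p = 0.609). They were Il2, a T cell growth factor, by 3.21 ± 0.58 (adjusted p = 0.0131), and Ccl4 by 1.47 ± 0.291 (adjusted p = 0.0229). Zfp683, which codes for the residency factor Hobit, fell by 2.98 ± 0.501 (adjusted p = 0.00917), and the ILC1 and residency genes shifted down with only this 1 of 17 called, and 6 lower adjusted over the list alone. Their median was −0.682 (adjusted p = 7.53e-06, or 0.116 with an estimated correlation). S1pr5 fell by 1.26 ± 0.215 (adjusted p = 0.00995) and the skin-homing receptor Ccr10 by 2.42 ± 0.52 (adjusted p = 0.0331), the 2 lower of 16 homing receptors, with 6 lower and 1 higher adjusted over the list alone. Their median was −0.508 (adjusted p = 3.93e-05, or 0.116 with an estimated correlation). Of 16 NK cell genes 1 fell, and 2 adjusted over the list alone. Their median was −0.513 (adjusted p = 8.41e-05, or 0.116 with an estimated correlation). Ncr1 was not called (−0.80, adjusted p = 0.218), but was under quantile normalization (adjusted p = 0.0295) and in the authors' table (adjusted p = 0.000198). Further falls were Cyp2f2 (−4.24 ± 0.868, at least 6.58-fold), the complement gene C4b (−2.92 ± 0.588) and the sialyltransferase St6gal1 (−2.75 ± 0.569).

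Glycolysis and hypoxia genes shifted up in tumor lesions with 0 of 24 called, and 2 higher adjusted over the list alone. Their median was 0.59 (adjusted p = 9.29e-08, or 0.116 with an estimated correlation). Of 28 interferon-stimulated genes 1 rose, and 2 adjusted over the list alone. Their median was 0.633 (adjusted p = 9.29e-08, or 0.34 with an estimated correlation). Beside them keratinocyte markers shifted up, 1 of 14 called, also adjusted over the list alone (median 0.758, adjusted p = 0.0138, or adjusted p = 0.604 with an estimated correlation). Endothelial markers shifted up with 0 of 5 called and 2 adjusted over the list alone (median 0.897, adjusted p = 0.00541, or adjusted p = 0.17 with an estimated correlation). All 39 and 86 genes kept their direction within slides 1 and 2, fixed as their arrays did not overlap. On these slides Jchain differed by −4.20 and −4.87, and Gzme by 7.10 and 4.99.

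With slide as a block 239 genes were called, 117 of the 125 among them, and 192 in the fit with the replicate number as a block, all 125 among them. Of the named genes Ccr10, Cxcl13, Cyp2f2, Dao and Ugt1a10 lost the call with normexp, Ccr10 under quantile normalization, Cd68 with slide as a block, Cd68, Dao and Ugt1a10 with probe means, and Cd68, Cxcl13, Cyp2f2, Il2, Oasl2, Pmepa1 and Ugt1a10 without slide 2. The count depended on single arrays: 41 to 233 genes leaving out replicates. Of the 22 called genes named, 9 kept the call without skin replicate 3 (Gzmd, Gzme and Gzmg among them, Gzmf not), 11 without skin replicate 2, 14 without tumor replicate 1 and 17 to 21 without the others. Of the list shifts, interferon-stimulated genes lost the call without tumor replicate 1, keratinocyte markers without skin replicates 1 and 3, endothelial markers without skin replicate 1, and both without slide 2 and tumor replicates 2 and 3.

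Papilloma lesions (n = 2) were compared with the skin of papilloma mice (n = 3) to show the same step in benign lesions. Of 21047 genes tested, 1592 were higher and 1147 lower in papillomas, 309 of the higher ones well above background on no array of the skin. Some genes of ILC2 and ILC3, the lymphocytes that make type 2 cytokines and interleukins 17 and 22, were higher. Il13 rose by 5.41 ± 1.47 (adjusted p = 0.0261), at least 11.9-fold, Il17a by 4.77 ± 1.23 (adjusted p = 0.0211), and Il17f by 3.77 ± 0.885 (adjusted p = 0.0142). So did Il4 by 3.79 ± 0.745 (adjusted p = 0.00583), Il22 by 2.23 ± 0.586 (adjusted p = 0.0231) and Ptgdr2, the prostaglandin D receptor of type 2 cells, by 4.29 ± 0.781 (adjusted p = 0.00421, at least 6.1-fold). Kit rose by 2.64 ± 0.338 (adjusted p = 0.000463), Ahr, a transcription factor that maintains ILC3, by 1.38 ± 0.296 (adjusted p = 0.00908), and Nrp1 by 2.44 ± 0.654 (adjusted p = 0.0247). Of 11 ILC3 genes 5 rose, and 6 adjusted over the list alone. Their median was 2.26 (adjusted p = 0.000966, or 0.316 with an estimated correlation). Of 12 ILC2 genes 3 rose, and 7 adjusted over the list alone. Their median was 1.02 (adjusted p = 0.00389, or 0.355 with an estimated correlation). Of 17 ILC1 and residency genes 3 rose and 1 fell, and 5 and 1 adjusted over the list alone, with the residency receptor Cxcr6 up by 1.75 ± 0.46 and the death ligand Tnfsf10 (TRAIL) up by 1.08 ± 0.276. Their median was 0.767 (adjusted p = 0.0129, or 0.514 with an estimated correlation). Mast cell markers rose beside these groups, 2 of 8 also adjusted over the list alone, with the tryptase Tpsab1 up by 4.35 ± 1.35 (adjusted p = 0.0431, at least 6.94-fold). Their median was 1.98 (adjusted p = 0.0391, or 0.555 with an estimated correlation). So did dendritic and Langerhans cell markers as a list, with 0 of 12 called (median 1.47, adjusted p = 0.025, or adjusted p = 0.556 with an estimated correlation). Il17a, Il17f, Il4 and Nrp1 were well above background on 1 of 3 skin arrays. With normexp 21 of the 41 called genes named lost the call, among them Il13, Il17a, Il17f, Il4, Il22, Ptgdr2, Nrp1 and Havcr2.

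NK cell genes fell in papillomas. Ncr1 itself fell by 1.06 ± 0.278 (adjusted p = 0.0225), the activating receptor Klra8 by 2.39 ± 0.477 (adjusted p = 0.00627) and the maturation marker Klrg1 by 2.11 ± 0.357 (adjusted p = 0.00296). Klrb1c (NK1.1) fell by 1.57 ± 0.279 (adjusted p = 0.00385) and the transcription factor Eomes by 1.34 ± 0.334 (adjusted p = 0.0189). Of 16 NK cell genes 9 fell and 0 rose, and 11 fell and 1 rose adjusted over the list alone. Their median was −1.17 (adjusted p = 9.35e-06, or 0.235 with an estimated correlation). Of 16 activating receptors and signalling genes 7 fell, also adjusted over the list alone. Their median was −0.543 (adjusted p = 0.00243, or adjusted p = 0.355 with an estimated correlation, and adjusted p = 0.136 in the authors' table). The cytotoxic genes Nkg7, Prf1 and Gzmb fell by 1.81 ± 0.423, 1.69 ± 0.328 and 1.55 ± 0.305. Of 12 cytotoxic effectors 5 fell and 2 rose, and 6 and 2 adjusted over the list alone. Their median was −0.637 (adjusted p = 0.0304, or adjusted p = 0.555 with an estimated correlation; adjusted p = 0.446 under quantile normalization, 0.222 in the authors' table and 0.11 without slide 2). Inhibitory and regulatory receptors went both ways: Tigit fell by 1.55 ± 0.373, Klre1 by 2.27 ± 0.335 and Il21r by 1.93 ± 0.39, while Havcr2 (TIM-3) rose by 4.54 ± 1.33 (at least 8.43-fold). The enzyme Nt5e rose by 2.16 ± 0.311. Tnfsf11 (RANKL) rose by 3.74 ± 0.699 and Ccl4 fell by 2.26 ± 0.326. Of 30 cell cycle genes 14 fell, and 21 adjusted over the list alone, such as Ccna2 by 1.73 ± 0.368 and Ube2c by 1.49 ± 0.377. Their median was −0.95 (adjusted p = 1.73e-09, or 0.425 with an estimated correlation).

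The largest rises were those of Adamdec1, a metalloprotease of myeloid cells (7.88 ± 1.35, adjusted p = 0.00316, at least 81.7-fold), Fam50b (5.53 ± 0.838, adjusted p = 0.00159, at least 9.92-fold) and Trpm3 (5.41 ± 1.16, adjusted p = 0.00896, at least 8.996-fold). The largest falls were those of Jchain (−8.53 ± 1.18, adjusted p = 0.000787), the milk protein Csn3 (−7.40 ± 2.3, adjusted p = 0.043, at least 35.0-fold) and Igfbp3 (−6.12 ± 1.5, adjusted p = 0.0174, at least 17.4-fold). Of 55 immunoglobulin transcripts, a class chosen after the values were seen, 18 were lower and 2 higher. Olfr1107 rose by 5.21 ± 0.758 (adjusted p = 0.00112, at least 9.67-fold) with 50 of 192 tested olfactory and vomeronasal receptor genes, a class also chosen after the values were seen, whose median was 1.33 but −0.0245 under quantile normalization and −0.108 in the authors' table, where its direction turned. The keratin Krt5 fell by 4.21 ± 1.33. Of 9 fibroblast markers 3 fell, and 4 adjusted over the list alone, Col3a1 by 3.61 ± 0.929 and Dcn by 3.39 ± 1.09. Their median was −2.18 (adjusted p = 0.00389, or adjusted p = 0.555 with an estimated correlation; adjusted p = 0.168 in the authors' table). The globins Hbb-b2 and Hba-a1 fell by 1.84 ± 0.553 and 1.80 ± 0.568, 2 of 5 erythroid genes and 4 adjusted over the list alone. Their median was −1.82 (adjusted p = 0.0352, or adjusted p = 0.556 with an estimated correlation; adjusted p = 0.0894 in the authors' table).

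Papilloma lesions shared no slide with the skin of papilloma mice, so no within-slide value exists. Further calls lost were those of Eomes, Ncr1, Nrp1, Il22, Dcn and both globins under quantile normalization, of Klra8, Klrb1c, Csn3, Igfbp3 and Krt5 with probe means, of Csn3, Dcn, Krt5, Tpsab1 and Hba-a1 without the filter, of both globins with the replicate block, of Csn3, Igfbp3, Havcr2, Col3a1, Dcn, Krt5 and Hbb-b2 with slide as a block, and of 6 genes without slide 2. With slide as a block 3387 genes were called, 1821 of the 2739 among them, and fibroblast (adjusted p = 0.398) and erythroid markers (adjusted p = 0.118) lost their call. Much of the count rested on papilloma replicate 2. Without it 246 genes were called, 214 of them among the 2739, and 12 of the 41 called genes named kept the call. Without papilloma replicate 1, 13001 genes were called and 37 of the 41 kept, and without skin replicate 3, 1028 genes and 28 of the 41. Of the list shifts named, those of ILC1, ILC2, ILC3, dendritic cell, mast cell and erythroid genes were lost without papilloma replicate 1, those of ILC1, dendritic cell, mast cell and erythroid genes without skin replicate 1, that of cytotoxic effectors without papilloma replicate 2, those of cytotoxic effectors and erythroid genes without skin replicate 3, and those of ILC1, dendritic cell and mast cell genes without the filter. Quantile normalization shifted the median of all genes by −0.115 and the authors' table by −0.136, and the share of called genes that were higher was 58.1% here, 40.7% and 37.2% under these, and 29.2% of 643 with normexp.

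Whether the lesion step differed between tumor and papilloma mice was tested directly, as the difference of the lesion effects. Of 21424 genes, 36 differed. Spp1 (osteopontin, a secreted matrix protein) differed by 5.54 ± 1.08 (adjusted p = 0.0492), with an effect of 2.38 in tumors that was not called (adjusted p = 0.194) and of −3.16 in papillomas that was (adjusted p = 0.0203). Gpr15 differed by −5.15 ± 0.69 (adjusted p = 0.00796), with effects of −1.36 in tumors and 3.79 in papillomas. Il4 differed by −5.04 ± 0.999 (adjusted p = 0.0492; effects of −1.26 and 3.79) and Zfp683 by −3.77 ± 0.752 (adjusted p = 0.0492; effects of −2.98 and 0.79). Among genes of lymphocyte differentiation, Slamf6 differed by 1.92 ± 0.376, the interferon regulatory factor Irf8 by 1.59 ± 0.303 and the lymphocyte GTPase Gimap7 by 2.38 ± 0.337 (adjusted p = 0.00796). Tmsb15a, Bspry, Ruvbl2 and Tesc differed by 3.22, 2.58, 1.87 and 1.77, and Togaram2, Il20ra, Dmrta1 and Nebl by −4.37, −3.87, −3.19 and −2.94. Il4 in tumor lesions and Tmsb15a in papilloma lesions were not well above background on any array, so their differences rest on background values there. ILC1 and residency genes shifted down, 1 of 17 called and 9 adjusted over the list alone (median −1.11, adjusted p = 4.27e-06, or adjusted p = 0.283 with an estimated correlation). Cytotoxic effectors shifted up with 0 of 16 called, and 8 higher and 1 lower adjusted over the list alone (median 1.1, adjusted p = 0.000441, or adjusted p = 0.284 with an estimated correlation). Cell cycle genes shifted up with 0 of 30 called and 19 adjusted over the list alone. Their median was 1.15 (adjusted p = 7.62e-13, or adjusted p = 0.284 with an estimated correlation). ILC2 and ILC3 genes shifted down with 1 of 13 and 0 of 11 called, and 2 and 0 adjusted over the list alone (medians −1.12 and −1.63, adjusted p = 0.00361 and 0.00168, or adjusted p = 0.284 each with an estimated correlation). Beside these, dendritic and Langerhans cell and B cell markers shifted down with 0 of 12 and 0 of 9 called (medians −1.43 and −1.53, adjusted p = 0.028 each, or adjusted p = 0.632 and 0.296 with an estimated correlation). Keratinocyte markers shifted up, 0 of 15 and 4 adjusted over the list alone. Their median was 3.01 (adjusted p = 0.000441, or adjusted p = 0.446 with an estimated correlation).

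The count depended on single arrays. Without papilloma replicates 1 and 2 it was 5714 and 4, and without tumor replicates 1, 2 and 3 it was 5, 168 and 151. Of the 15 genes named, 2 (Gimap7 and Gpr15) kept the call without papilloma replicate 2, 3 each without skin of tumor mice replicates 1 and 2 and skin of papilloma mice replicate 3, and 4 without tumor replicate 1. The shifts of ILC1, ILC2, ILC3, dendritic cell and B cell genes were lost without papilloma replicate 1, that of ILC2 genes also without tumor replicate 1, and those of dendritic cell and B cell markers with probe means and without 4 and 5 of the 11 replicates in turn, the latter also under quantile normalization and without slide 2. A fit with slide as a block called 1005 genes, all 36 among them. With normexp 17 were called, 10 of the 36 among them and 70.6% higher against 47.2% here, and without the filter on dim probes 6. Of the 15 genes named, Spp1, Bspry and Gimap7 kept the call with normexp, and Gimap7, Gpr15 and Nebl without the filter. It was lost by Slamf6, Togaram2 and Irf8 under quantile normalization, Togaram2 with probe means and Dmrta1 without slide 2. The authors' table shifted the median of all genes by 0.109 and called 7648, 59.6% of them higher.

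Of 17496 genes tested in both lesion types, 612 rose in papillomas and 33 in tumors, 16 in both, against 1.15 for independent sets. Of 1143 and 81 lower genes 35 were shared, against 5.29, but these hold immunoglobulin transcripts, which are not independent. Another 3 were called in opposite ways. The shared count of 51 became 24 without papilloma replicate 2 and 15 without skin of tumor mice replicate 3.

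Tumor lesions (n = 3) were set against papilloma lesions (n = 2) to compare malignant with benign growth. Of 20952 genes tested, 2257 were higher and 2431 lower in tumors, 540 of the lower ones well above background on no tumor array. The granzymes Gzme, Gzmf, Gzmd and Gzmg rose by 8.32 ± 0.895 (adjusted p = 0.000142), 6.80 ± 1.06 (adjusted p = 0.00142), 5.25 ± 1.17 (adjusted p = 0.00679) and 5.11 ± 0.905 (adjusted p = 0.00232), Gzmb by 1.58 ± 0.305 (adjusted p = 0.00341) and Prf1 by 1.69 ± 0.328 (adjusted p = 0.00352). In papillomas the first 4 were well above background on replicate 2 alone, so sizes and order are uncertain. Of 16 cytotoxic effectors 8 rose and 2 fell, and 9 and 2 adjusted over the list alone. Their median was 0.973 (adjusted p = 0.000623, or 0.276 with an estimated correlation). Proliferation genes rose with them: Tk1 by 2.43 ± 0.305, Ccna2 by 2.37 ± 0.368, the mitotic kinase Plk1 by 2.33 ± 0.301, Ube2c by 2.17 ± 0.377 and Mki67 by 1.77 ± 0.404, in all 25 of 30 cell cycle genes, and 28 adjusted over the list alone. Their median was 1.76 (adjusted p = 3.15e-20, or 0.276 with an estimated correlation). Of 24 glycolysis and hypoxia genes 12 rose and 1 fell, and 14 and 1 adjusted over the list alone, with the lactate transporter Slc16a3 up by 2.72 ± 0.679 and the enzymes Pkm, Gapdh and Pgk1 by 1.91 ± 0.518, 1.90 ± 0.347 and 1.88 ± 0.334. Their median was 1.13 (adjusted p = 6.9e-05, or 0.276 with an estimated correlation). The inhibitory receptors Tigit and Lag3 rose by 2.70 ± 0.373 (adjusted p = 0.000652) and 1.48 ± 0.496 (adjusted p = 0.0403). Of 16 NK cell genes 5 rose and 1 fell, and 6 and 1 adjusted over the list alone, with Klra8 up by 1.83 ± 0.477, Klrg1 by 1.30 ± 0.357 and Eomes by 1.26 ± 0.334. Their shift was not called (median 0.383, adjusted p = 0.148, and 0.00554 without the filter on dim probes). Spp1 rose by 4.07 ± 0.806 and Zbtb32, a repressor in activated lymphocytes, by 4.34 ± 0.992.

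ILC1, ILC2 and ILC3 lists shifted down from papillomas to tumors. Of 17 ILC1 and residency genes 9 fell and 1 rose, and 12 and 1 adjusted over the list alone, with Zfp683 down by 2.40 ± 0.561, Il7r by 2.27 ± 0.618, Cxcr6 by 1.94 ± 0.46, Ccr8 by 1.93 ± 0.683 and Tnfsf10 by 1.37 ± 0.276. Their median was −1.09 (adjusted p = 0.000576, or 0.276 with an estimated correlation). Of 12 ILC2 genes 4 fell, also adjusted over the list alone, Il4 by 4.90 ± 0.745 (at least 10.2-fold), Ptgdr2 by 3.31 ± 0.781 and Gata3, the ILC2 master regulator, by 0.80 ± 0.236. Their median was −1.37 (adjusted p = 0.00243, or 0.276 with an estimated correlation). Of 11 ILC3 genes 1 fell, also adjusted over the list alone, Il17f by 3.02 ± 0.885 (list median −1.47, adjusted p = 0.0142, or adjusted p = 0.322 with an estimated correlation). Il2 fell by 2.92 ± 0.649. The largest falls were those of Adamdec1 (−6.04 ± 1.35), Trpm3 (−5.43 ± 1.16, at least 9.32-fold), Serpinb2 (−5.35 ± 0.938), Olfr1317 (−5.19 ± 1.03, at least 7.69-fold) and Fam50b (−4.94 ± 0.838, at least 10.3-fold). Of 12 dendritic and Langerhans cell markers 2 fell beside the ILC genes, and 3 adjusted over the list alone (median −1.66, adjusted p = 0.0142, or adjusted p = 0.548 with an estimated correlation). Erythroid genes rose beside the granzymes, 4 of 5 also adjusted over the list alone: Hba-a1 by 3 ± 0.568, the heme enzyme Alas2 by 2.87 ± 0.641, Hbb-bt by 2.82 ± 0.602 and Hbb-b2 by 2.58 ± 0.553. Their median was 2.82 (adjusted p = 0.00243, or 0.322 with an estimated correlation).

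On slide 5 (tumor and papilloma replicate 1) 2254 of the 2257 higher and 2398 of the 2431 lower genes kept their direction. For 4578 of the 4688 this was fixed, as their arrays did not overlap. With slide as a block 5825 genes were called, 3920 of the 4688 among them. Without papilloma replicate 2, 364 genes were called, 320 of them among the 4688, and 16 of the 41 called genes named kept the call, again with a lone papilloma sample; without papilloma replicate 1, 14993 genes were called and 39 of the 41 kept. The shifts of ILC2, ILC3 and dendritic cell genes were lost without tumor replicate 1, these and that of ILC1 genes without papilloma replicate 1, and those of ILC3 and dendritic cell genes without the filter. Calls were lost with normexp by Olfr1317, Lag3, Ptgdr2, Gata3, Il17f and Klrg1, under quantile normalization by Il17f, Klra8, Klrg1 and Eomes, with slide as a block by Lag3 and Gata3, with probe means by Tk1 and Klra8, without the filter by Lag3 and Ccr8, and without slide 2 by Lag3. Quantile normalization shifted the median of all genes by 0.113 and the authors' table by 0.116; 48.1% of the called genes were higher here, 65% and 62% under these, and 77.7% of 2433 with normexp.

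Skin of mice given PMA only served as the control without carcinogen. Against it (n = 2), papilloma lesions (n = 2) had 928 higher and 948 lower genes of 21574, 459 of the higher ones well above background on no control array. Cytokines of ILC2 and ILC3 rose, Il13 by 5.93 ± 1.61 (adjusted p = 0.0305, at least 13.7-fold), Il17a by 5.27 ± 1.34 (adjusted p = 0.0227), Il17f by 4.97 ± 0.97 (adjusted p = 0.00611, at least 10.2-fold) and Il4 by 4.22 ± 0.816 (adjusted p = 0.00589). So did Tnfsf11 by 4.58 ± 0.766 (at least 17.5-fold), Ptgdr2 by 4.55 ± 0.855 (at least 7.05-fold), Cxcr6 by 2.08 ± 0.504, Itga1 by 1.84 ± 0.554 and Ahr by 1.72 ± 0.324. Of 11 ILC3 genes 6 rose, also adjusted over the list alone (median 2.15, adjusted p = 3.06e-05, or adjusted p = 0.117 with an estimated correlation). Of 13 ILC2 genes 4 rose, and 7 adjusted over the list alone (median 1.36, adjusted p = 0.000308, or adjusted p = 0.144 with an estimated correlation). Of 17 ILC1 genes 3 rose and 1 fell, and 7 and 1 adjusted over the list alone (median 0.859, adjusted p = 0.000743, or adjusted p = 0.213 with an estimated correlation). Of 16 NK cell genes 8 fell, and 11 adjusted over the list alone, Klra8 by 2.99 ± 0.523, Klrg1 by 2.70 ± 0.391, S1pr5 by 1.61 ± 0.264 and Ncr1 by 1.10 ± 0.305 (adjusted p = 0.0326). Their median was −1.15 (adjusted p = 7.43e-07, or 0.117 with an estimated correlation). Gzmb and Prf1 fell by 1.89 ± 0.334 and 1.68 ± 0.359. Of 30 cell cycle genes 25 fell, and 29 adjusted over the list alone, Ccna2 by 2.44 ± 0.403, Birc5 by 2.37 ± 0.38, Ccnb1 by 2.28 ± 0.412 and Mki67 by 2.21 ± 0.442. Their median was −1.64 (adjusted p = 3.45e-20, or 0.134 with an estimated correlation). Markers of other cells moved beside them. Of 9 neutrophil markers 1 rose, Ly6g by 3.01 ± 0.723, at least 6.99-fold (list median 3.01, adjusted p = 0.0173, or adjusted p = 0.536 with an estimated correlation). Of 8 mast cell markers 1 rose, and 5 adjusted over the list alone. Their median was 2.54 (adjusted p = 0.003, or 0.252 with an estimated correlation). Of 12 macrophage and monocyte markers 1 rose, also adjusted over the list alone (median 1.79, adjusted p = 0.0173, or adjusted p = 0.626 with an estimated correlation). The muscle genes Tnnc2 and Acta1 fell by 4.40 ± 1.03 and 4.13 ± 1.22. The largest rises were Adamdec1 (7.62 ± 1.48, at least 93.7-fold), Ifitm1 (6.76 ± 1.07) and Mettl7b (5.58 ± 1.13, at least 9.94-fold), and Jchain fell by 5.601 ± 1.29.

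On slide 3 (papilloma replicate 2, PMA-only skin) 923 of the 928 and 945 of the 948 genes kept their direction. With normexp 9 of the 26 called genes named lost the call (Il13, Il17a, Il17f, Il4, Ptgdr2, Itga1, Ly6g, Mettl7b and Acta1), under quantile normalization Ncr1 and Ly6g, without the filter Acta1 and Itga1, and with slide as a block Itga1. In the fit with slide as a block 5244 genes were called, 1858 of the 1876 among them. Without papilloma replicate 2, 284 genes were called and 10 of the 26 called genes named kept the call. Called genes numbered, without PMA-only skin replicates 1 and 2, 140 and 195, with 8 and 12 of the 26 kept, and without papilloma replicate 1, 13196, with 23 of the 26 kept. The shifts of ILC1, ILC2, ILC3, neutrophil, macrophage and mast cell genes were lost without papilloma replicate 1, that of macrophage markers without PMA-only skin replicate 1, and those of neutrophil and macrophage markers without the filter and with probe means. Quantile normalization shifted the median of all genes by −0.169 and the authors' table by −0.154; of the called genes 49.5% were higher here, 28.5% and 34.7% under these, and 19.6% of 662 with normexp.

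Tumor lesions (n = 3) against PMA-only skin (n = 2) had 101 higher and 77 lower genes of 20086. Gzme rose by 9.33 ± 0.895 (adjusted p = 3.35e-05), Gzmf by 8.53 ± 1.06 (adjusted p = 0.000531), Gzmd by 8.07 ± 1.17 (adjusted p = 0.00199) and Gzmg by 7.15 ± 0.905 (adjusted p = 0.000531). Gzmf, Gzmd and Gzmg were at least 93.2-fold, 64.1-fold and 55.0-fold higher. The 16 cytotoxic effectors counted these 4 rises, with 4 higher and 1 lower adjusted over the list alone. Their median was 0.142 (adjusted p = 0.000618, or 0.242 with an estimated correlation). Inhibitory receptors rose, Pdcd1 by 4.13 ± 0.953 (adjusted p = 0.0449), Lag3 by 2.54 ± 0.496 (adjusted p = 0.0159), Tigit by 2.19 ± 0.373 (adjusted p = 0.00627) and Nt5e by 1.88 ± 0.311 (adjusted p = 0.00595), 4 of 17, and 6 higher and 1 lower adjusted over the list alone. Their median was 0.324 (adjusted p = 0.000792, or 0.0882 with an estimated correlation). Kit rose by 1.87 ± 0.338, Pmepa1 by 2.74 ± 0.475, Ccl1 by 4.61 ± 0.913, Zbtb32 by 4.58 ± 0.992 and the interferon-induced Ifitm1 and Oasl2 by 6.48 ± 0.977 and 3.02 ± 0.601. Among NK cell genes S1pr5 fell by 2.18 ± 0.241 (adjusted p = 0.000207) and Cd247, the zeta chain of activating receptors, by 1.24 ± 0.229. They were the 2 called of 16, and 7 fell adjusted over the list alone. Their median was −0.736 (adjusted p = 2.52e-06, or 0.0882 with an estimated correlation). Ncr1 was not called (−0.71, adjusted p = 0.276), but was under quantile normalization (adjusted p = 0.0499) and in the authors' table (adjusted p = 0.00204). Il2, Ccr10 and Ccl4 fell by 3.39 ± 0.649, 3.09 ± 0.581 and 1.92 ± 0.326. Glycolysis genes shifted up with 0 of 24 called and 13 adjusted over the list alone. Their median was 0.941 (adjusted p = 3.75e-10, or 0.0882 with an estimated correlation). Markers of other cells moved beside these. Of 9 neutrophil markers 1 rose, Ly6g by 4.10 ± 0.66 (at least 14.9-fold), and 4 adjusted over the list alone (median 2.57, adjusted p = 1.68e-05, or adjusted p = 0.232 with an estimated correlation). Of 5 erythroid genes 3 rose, Alas2 by 2.96 ± 0.641, Hbb-bt by 2.57 ± 0.602 and Hba-a1 by 2.499 ± 0.568, and 4 adjusted over the list alone. Their median was 2.5 (adjusted p = 5.2e-07, or 0.0882 with an estimated correlation). Of 6 endothelial markers 1 rose, also adjusted over the list alone (median 1, adjusted p = 0.0492, or adjusted p = 0.305 with an estimated correlation). Macrophage and monocyte markers shifted up with 0 of 8 called and 1 adjusted over the list alone (median 0.953, adjusted p = 0.0338, or adjusted p = 0.536 with an estimated correlation). Both calls were lost with slide as a block, in the authors' table and without slide 2, tumor replicates 2 and 3 and PMA-only skin replicate 1. Krt6b rose by 4.64 ± 0.589, and the muscle genes Myl1, Myh8 and Tnnc2 fell by 6.49 ± 1.09 (at least 27.8-fold), 5.16 ± 1.19 and 4.45 ± 0.77.

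These groups shared no slide. With slide as a block 76 genes were called, 61 of the 178 among them, and 13 of the 27 called genes named kept the call. Gzme, Gzmf, Gzmd, Gzmg, Ifitm1, Krt6b, S1pr5, Kit, Nt5e, Ccl4, Myl1, Tnnc2 and Alas2 did, and Pdcd1, Lag3 and Tigit (adjusted p = 0.23, 0.0977 and 0.0796) did not. Without PMA-only skin replicates 1 and 2, 12 and 29 genes were called and 5 and 9 of the 27 kept. Without tumor replicate 1, 384 genes were called and 26 kept, and without tumor replicates 2 and 3, 21 each. With normexp 69% of the called genes were higher, against 56.7%, and Myh8 and Pdcd1 lost the call. Others lost were those of Hbb-bt under quantile normalization, Pdcd1 and Hbb-bt with the replicate block, Ccl1, Myh8 and Cd247 with probe means, Myh8, Pdcd1, Hbb-bt and Hba-a1 without the filter, and Myh8, Alas2, Hbb-bt and Hba-a1 without slide 2.

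Skin of tumor and papilloma mice was set against PMA-only skin to ask what the carcinogen changes outside the lesions. In skin of papilloma mice (n = 3) 10 of 20130 genes rose and 0 fell, with 1104 at an unadjusted p under 0.05 in limma, and by their description all 10 were immunoglobulin transcripts. In skin of tumor mice (n = 3) 6 of 20258 rose and 0 fell, with 669 at an unadjusted p under 0.05: 5 immunoglobulin transcripts and Itgb3, an integrin chain (1.60 ± 0.269, adjusted p = 0.043). Over all immunoglobulin transcripts, a class chosen after the values were seen, the medians were 3.08 over 44 in papilloma mice and 3.16 over 62 in tumor mice (1.85 and 1.5 with normexp, 2.06 each in the authors' table). Erythroid genes shifted up in both, with 0 of 5 called and 4 adjusted over the list alone in each. Their medians were 1.53 and 2.59 (adjusted p = 5.27e-05 and 3.57e-13, or 0.392 and 0.0283 with an estimated correlation). Inhibitory receptors were called as a list in both, lost in papilloma mice without each skin replicate in turn. In tumor mice they shifted up with 0 of 16 called and 2 adjusted over the list alone, and ILC1 genes with 0 of 17. Their medians were 0.402 and 0.642 (adjusted p = 0.000121 and 1.24e-05, or 0.0283 and 0.0979 with an estimated correlation). Beside them neutrophil markers shifted up, 0 of 12 called and 5 adjusted over the list alone (median 3.4, adjusted p = 1.08e-10, or adjusted p = 0.0979 with an estimated correlation). Cell cycle genes shifted down in papilloma mice, 0 of 30 called in either way of adjusting. Their median was −0.73 (adjusted p = 5.84e-13, or adjusted p = 0.392 with an estimated correlation). Beside them keratinocyte and fibroblast markers shifted up, 0 of 12 and 0 of 9 called in either way (medians 1.17 and 0.982, adjusted p = 0.0135 and 0.0263, or adjusted p = 0.684 each with an estimated correlation), both calls lost with slide as a block, in the authors' table and without skin replicate 2 and PMA-only skin replicate 1, and that of fibroblast markers without skin replicate 3 and slide 2. These groups shared no slide, and with slide as a block no gene was called in either (Itgb3 at adjusted p = 0.726). Leaving out replicates gave 0 to 20 genes in papilloma mice and 0 to 7 in tumor mice, with at most 1 in each without either PMA-only skin replicate, and Itgb3 also lost its call without skin replicate 2, without slide 2 and with probe means. The erythroid shift of papilloma mice was lost without PMA-only skin replicate 1.

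Between skin of tumor mice and skin of papilloma mice (n = 3 each) limma called 0 of 17766 genes, with 742 at an unadjusted p under 0.05. Cell cycle genes were shifted up in tumor mice with 0 of 30 called (median 0.562, adjusted p = 2.72e-14, or 0.503 with an estimated correlation). So were neutrophil markers, 0 of 12 called and 2 adjusted over the list alone (median 2.97, adjusted p = 7.11e-06, or adjusted p = 0.503 with an estimated correlation). Erythroid genes were shifted up with 0 of 5 called (median 1.06, adjusted p = 0.0013, or 0.503 with an estimated correlation). Keratinocyte markers were shifted down with 0 of 11 called (median −1.63, adjusted p = 3.38e-06, or 0.503 with an estimated correlation). The calls of keratinocyte and erythroid genes were lost without skin of papilloma mice replicate 2, the latter also without skin of tumor mice replicate 1.

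The draining lymph nodes were compared to ask whether NKp46+ cells away from the lesion differ with the disease (n = 3 in each group). In tumor mice against PMA-only mice 5 of 21358 genes rose and 0 fell. They were Gadd45g, a growth arrest and stress gene, by 1.78 ± 0.206 (adjusted p = 0.0013), the immunoglobulin-like receptor Lilr4b by 2.32 ± 0.299 (adjusted p = 0.00318) and the histone H3c8 by 2.36 ± 0.322 (adjusted p = 0.00476), followed by the DNA synthesis enzyme Tk1 by 1.65 ± 0.272 (adjusted p = 0.039) and Gzmb by 1.64 ± 0.273 (adjusted p = 0.039). Of 30 cell cycle genes 1 rose, and 28 adjusted over the list alone. Their median was 1.22 (adjusted p = 8.81e-45, or 0.0255 with an estimated correlation). Of 29 interferon-stimulated genes 0 were called, and 11 rose adjusted over the list alone. Their median was 1.05 (adjusted p = 8.88e-17, or 0.175 with an estimated correlation). Cytokines (median 0.512, adjusted p = 0.00163, or adjusted p = 0.306 with an estimated correlation) and inhibitory receptors (median 0.173, adjusted p = 0.00295, or adjusted p = 0.117 with an estimated correlation) had 0 called members and 3 higher each adjusted over the list alone. Erythroid genes shifted up beside them, 0 of 5 and 4 adjusted over the list alone. Their median was 2.03 (adjusted p = 7.71e-09, or 0.089 with an estimated correlation). Neutrophil markers did too, 0 of 9 and 1 adjusted over the list alone (median 1.64, adjusted p = 0.0293, or adjusted p = 0.481 with an estimated correlation), a call lost without slide 2, tumor node replicates 1 and 2, and PMA-only node replicates 1 and 3. On slides 1, 3 and 4 Gadd45g differed by 1.64, 1.81 and 1.89, Gzmb by 1.47, 1.33 and 2.14, and the medians were 0.687, 1.31 and 1.57 for cell cycle, 0.659, 1.42 and 1.48 for interferon-stimulated and 2.67, 0.589 and 3.04 for erythroid genes. With slide as a block 216 genes were called and without slide 2, which held no node array, 180, each with the 5 among them. The count of 5 thus depended on arrays of other tissues. Leaving out replicates gave 1 to 52 genes, Gadd45g alone without tumor node replicate 1, and under quantile normalization 3 of the 5 kept the call, with normexp all but Gzmb and with probe means all but Tk1.

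Lymph nodes of papilloma mice against PMA-only nodes had 0 called genes of 21100 in limma, with 750 at an unadjusted p under 0.05. The smallest p-values were those of Gadd45g (1.18 ± 0.206), H3c8 (1.81 ± 0.322) and Lilr4b (1.65 ± 0.299), each at adjusted p = 0.192. Cell cycle genes shifted up with 0 of 30 called and 23 adjusted over the list alone. Their median was 0.759 (adjusted p = 1.41e-29, or 0.0807 with an estimated correlation). Interferon-stimulated genes shifted up with 0 of 29 called (median 0.707, adjusted p = 4.22e-09, or 0.431 with an estimated correlation). Erythroid genes had 0 of 5 called and 4 higher adjusted over the list alone (median 1.69, adjusted p = 4.22e-09, or 0.0807 with an estimated correlation). Neutrophil markers shifted up with 0 of 9 called (median 1.76, adjusted p = 0.00541, or adjusted p = 0.431 with an estimated correlation), a call lost without papilloma node replicate 2 and PMA-only node replicate 3. Between nodes of tumor and of papilloma mice limma called 0 of 20570 genes, with 42 at an unadjusted p under 0.05. Cell cycle genes were shifted up in tumor mice with 0 of 30 called (median 0.374, adjusted p = 1.82e-18, or 0.377 with an estimated correlation). So were interferon-stimulated genes with 0 of 29 called (median 0.463, adjusted p = 6.79e-08, or adjusted p = 0.595 with an estimated correlation), a call lost without tumor node replicate 1.

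Naive skin, a single array with no replicate check, was set against the mean of both PMA-only skin arrays on the same slide. Over 20624 genes 376 differed by more than 2, 137 higher and 239 lower, while the median difference was 0.0859. The SD over genes was 0.599, not comparable with 0.621 between single PMA-only arrays, as a mean is less noisy. Neutrophil markers stood highest among lists (median 2.86, percentile 100 among 10000 random lists of matched expression), with S100a8 at 7.69 (well above background on 1 of both PMA-only arrays), and fibroblast markers lowest (median −2.9, percentile 0), with Lum at −4.54 (at least 13.1-fold lower) and Col1a1 at −3.67. Macrophage markers (0.811), cell cycle genes (0.444) and interferon-stimulated genes (0.451) were higher, each at percentile 100. Keratinocyte markers (−1.4) and immediate-early genes (−0.385) were lower, each at percentile 0. NK cell genes lay inside the range of random lists (0.0777, percentile 10.06). Jchain was at least 47.4-fold lower and not well above background in naive skin (−7.81), and Ncr1 differed by 0.28.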

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

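Of the tests below, those of the receptor, plasma cell and granzyme patterns were chosen after the result was seen, except the test for DNA, which was written before, as were the counts of other splits of the samples.

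The difference between the lesion effects of tumor and papilloma mice marked 36 genes for a closer look, by the limma test of that difference. The differences, tumor minus papilloma, were 5.54 for Spp1, 3.22 for Tmsb15a, 2.58 for Bspry, 2.38 for Gimap7, 1.92 for Slamf6, 1.87 for Ruvbl2, 1.77 for Tesc and 1.59 for Irf8. They were −5.15 for Gpr15, −5.04 for Il4, −4.37 for Togaram2, −3.87 for Il20ra, −3.77 for Zfp683, −3.19 for Dmrta1 and −2.94 for Nebl. Without papilloma replicate 2, which stood apart from the other arrays, 4 genes were called.

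Olfactory and vomeronasal receptor genes, genes of sensory neurons, were brighter in papilloma lesions than in the skin of papilloma mice. On papilloma replicate 1, 15.36% of the 1380 receptor genes were well above background, inside the 3.84% to 26.45% of the 21 arrays of other groups, so a raised floor on papilloma replicate 2 alone may account for the share above background. Without that replicate 12 receptor genes were called higher, against 2.44 expected from their share of the genes tested, and 8 of the 50 called with both replicates were among them. As these 12 rest on a single papilloma array, their source stays open. For the share on replicate 2, a difference of slides is argued against by its 70.07% against at most 16.3% on the other arrays of its slide; how this test was read was changed after the values were seen, because by this share replicate 1 lies within the other arrays. DNA in both papilloma preparations is argued against by intergenic regions with a probe on each strand, of which 58.2% were above background on both strands on replicate 1, within 28.21% to 80.6% elsewhere. On replicate 2 that share was 97.47% of 1067 regions, so DNA or non-specific material on that array stays open, as does a biological difference of papillomas, which was not tested.

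Jchain and immunoglobulin transcripts were lower in lesions than in the skin of tumor and papilloma mice. If plasma cells or their RNA in the skin samples were the cause, other plasma cell markers would fall too, and over 13 of them the median in tumor lesions was −0.07, with Mzb1 at −4.07 (adjusted p = 0.0602), Derl3 at −2.01 and Pou2af1 at −1.65. In papilloma lesions 4 of 13 were lower and 0 higher (median −0.744). Against PMA-only skin, where immunoglobulin transcripts were not lower, Creld2 and Txndc5 of these still were (−0.935 and −1.2). Xbp1 was not, and Pou2af1 was not tested, so this decides nothing. Nor does the tumor value, since 12 of the 13 were well above background on every tumor lesion array, which would hide a small share. The bound of −0.5 set for the test was wrong for that reason. Its reading was changed after the value was seen. A slide difference is argued against, as the smaller of both within-slide differences of Jchain was −4.2. A change of the sorted cells and fewer plasma cells in lesions than in skin of these mice both stay open and cannot be told apart.

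Gzmd, Gzme, Gzmf and Gzmg were higher in tumor lesions than in the skin of tumor mice. Whether a single transcript was read by all 4 probes stays open. Over arrays where both were well above background the differences of the Gzmd, Gzmf and Gzmg probes from the Gzme probe ranged over 4.5, 1.82 and 4.51. Without papilloma replicate 2 they ranged over 0.65, 1.54 and 2.16, on 4 or 5 arrays, and the noise of single probes is not known; this reading was changed after the values were seen. A slide difference is argued against by the smallest within-slide difference of 2.73, with skin values at background raised to the lowest signal well above it, a step added after the values were seen. Partial sharing of signal between the probes, and a different mix of cells in the sort, were not tested and stay open beside a change of the cells with tumor growth, which is a hypothesis found on the same data.

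The counts of called genes were compared with other splits of the same arrays. For skin against lymph node, with tissue exchanged within mouse states, 1 of 100 splits, the real one, called 8029 genes. The others called at most 1156, which argues against chance if arrays are independent. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. Tumor lesions against skin of tumor mice called 125 (1 of 10 splits as large), the highest other split 18, and of the splits that part all 3 numbered pairs the others called 0, 0 and 18. Lymph nodes of tumor mice against PMA-only nodes called 5 (1 of 10), the highest other 0. Lymph nodes of papilloma mice against PMA-only nodes and against nodes of tumor mice called 0 each (10 of 10), the highest other 0. Skin of tumor mice against skin of papilloma mice called 0 (10 of 10), while the highest other split called 61 and a further one 43. This points to a structure of the samples. Both keep the arrays of slide 4, the first skin samples of the tumor and papilloma mice, on the same side, as do 2 splits that called 1 each, so a part of the slides in it stays open. With slide as a block 0 genes were called.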

How the results depend on the processing

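Leaving out slide 2, the authors' table with slide as a block, and leaving out replicates for the overlap and for naive skin were chosen after seeing the data. The cause of each change was not tested, except that leaving out replicates leaves fewer arrays, and where 1 remains it is assumed to vary like the other groups.

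Called genes are given by comparison. Papilloma lesions against skin of papilloma mice had 643 with normexp, 11349 in the authors' table and 5809 there with slide as a block, against 2739, and 246 to 13001 leaving out replicates. Tumor lesions against skin of tumor mice had 239 with slide as a block, 192 with the replicate block, 2541 in the table and 827 with slide, against 125, and 41 to 233. Tumor against papilloma lesions had 2433 with normexp and 10816 in the table, against 4688, and 364 to 14993. Papilloma lesions against PMA-only skin had 662 with normexp, 5244 with slide, 2984 with the replicate block, 10414 in the table, 4913 without slide 2 and 7225 in the table with slide, against 1876, and 140 to 13196. Tumor lesions against it had 76 with slide, 4004 in the table, 347 without slide 2 and 544 in the table with slide, against 178, and 12 to 384. Skin of papilloma mice against it had 0 with slide, 310 in the table and 17 without slide 2, against 10, and 0 to 20. Skin of tumor mice against it had 10 with quantile normalization, 12 with normexp, 0 with slide, 377 in the table, 3 without slide 2 and 13 in the table with slide, against 6, and 0 to 7.

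Between both skins the table gave 667 and with slide 2, against 0 in every other setting. Lymph nodes of papilloma against PMA-only mice had 1 with slide, 1 without slide 2, 1088 in the table and 61 with slide, against 0. Nodes of tumor against PMA-only mice had 3 with quantile normalization, 11 with normexp, 216 with slide, 1662 in the table, 180 without slide 2 and 488 in the table with slide, against 5, and 1 to 52. Nodes of tumor against papilloma mice had 0 in every setting, with 42 at an unadjusted p under 0.05 in limma. Skin against lymph node had 12316 with normexp and 12824 in the table, against 8029, and 6541 to 8413. The difference of lesion effects had 213 with quantile normalization, 17 with normexp, 6 without the filter on dim probes, 95 with the mean of all probes, 1005 with slide, 200 with the replicate block, 7648 in the table, 244 without slide 2 and 3305 in the table with slide, against 36, and 3 to 5714. The overlap of 51 ranged from 15 to 76, and the naive skin lists, 18, from 14 to 17.

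Of 126 list shifts 3 kept the call with an estimated correlation; the number called ranged from 115 to 139 leaving out replicates. Quantile normalization kept 113 and normexp 114, while 103 stayed in the authors' table and 106 with slide as a block. Ribosomal proteins turned direction in papilloma lesions against skin of papilloma mice (adjusted p = 0.758 with quantile normalization, 0.965 in the table with slide) and in skin against lymph node (adjusted p = 0.557 with quantile normalization, 0.396 in the table, 0.43 there with slide). Leaving out replicates turned 7 calls, none of them under 0.05 once turned (ranges of the adjusted p over left-out replicates): immediate-early genes in tumor against papilloma lesions (adjusted p = 0.000682 to 0.438) and in nodes of tumor against papilloma mice (4.76e-09 to 0.888, and 0.785 without papilloma node replicate 2), cytokines in papilloma lesions against PMA-only skin (0.00587 to 0.961), interferon-stimulated genes in tumor lesions against it (1.71e-10 to 0.682), and keratinocyte markers in skin of papilloma mice against it (4.81e-09 to 0.896, and 0.707 without PMA-only skin replicate 1). Of genes near 0 that were not called, these changed sign: Gzmb in tumor lesions against skin (−0.0666 with slide, −0.0614 in the table, −0.075 there with slide, −0.22 to 0.28 leaving out replicates), Prf1 there (−0.0721 to 0.44) and Ncr1 in skin against lymph node (−0.11 to 0.0439).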
